A study of Arabidopsis thaliana with 9 samples.

How the data were processed

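Transcript levels were measured in 9 samples of Arabidopsis thaliana Col-0. Per the labels' protocols, cotyledons of 6-day-old seedlings were kept for 48 hours in VISUAL medium that held the GSK3 inhibitor bikinin at 10 µM, the cytokinin kinetin at 0.25 and the auxin 2,4-D at 1.25 mg per litre, and then moved to CC induction medium. That wording is the same for all 9 samples, so how the media of the 3 groups differed is not given in the sources used here. RNA was extracted with TRIzol and a column kit, turned into biotin-labelled cRNA and hybridised to one-colour Affymetrix arrays, per the labels' protocols.

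The authors' deposited table holds log2 signals for 38408 probe sets and 9 arrays, ranging from 0.0698 to 13.9. The submitters' processing notes name Affymetrix Expression Console; its version and the summary method are not given in the sources used here. The array medians and quartiles lie close together (medians 4.71 to 4.90), and the values were used as deposited, with no further normalization. The table carries no detection call and no mark for control probe sets, so all 38408 were tested, and neither background nor the ratio of 3' to 5' control probes could be read. All 9 columns were used, and 0 pairs of columns were identical; 4 probe sets have the same value on every array.

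Probe sets were named through a table of the platform's annotation, updated by gene number from a reference gene table of assembly TAIR10.1, which matched 16574 of the 16722 probe sets that name 1 gene. A further 759 name several genes and 20927 are unnamed here; no gene was named from either kind. The 16722 stand for 16550 genes. Naming was uneven: 85.8% of protein-coding genes that are known only by a locus tag have such a probe set, against 16.8% of those with a symbol. Of 259 genes in the 16 fixed lists 42 were measured. The lists of sieve element (15 genes), epidermis (7) and brassinosteroid-repressed genes (8) had 0 measured genes and were not analysed here. A block of 7083 low-numbered probe sets, all unnamed, varied more over the 9 arrays (median SD 0.524) than the rest (median SD 0.222). No build is stated for the arrays and no coordinates are given.

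Groups and replicate numbers came from the labels. The 3 comparisons (CC-S with VISUAL, CC-M with VISUAL, CC-S with CC-M) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided), all 9 arrays in 1 fit with a mean per group, 6 residual degrees of freedom and 2.65 prior ones. P-values were adjusted by Benjamini-Hochberg over all probe sets, and a call is an adjusted p under 0.05. Changes are differences of mean log2 signal, the group named first minus the other. Tables were prepared with Python 3.11.15 and pandas 2.3.3.

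The test was checked on simulated data, drawn independently for each probe set with its spread as estimated by the fit. For CC-S with VISUAL it recovered 66 of 100 probe sets changed by 1 on the log2 scale and 99 of 100 changed by 2. Beside these true calls it made 15 false ones, in a table of 38408 probe sets. For CC-S with CC-M it recovered 68 and 99 of 100, with 9 false calls. Under the Benjamini-Hochberg adjustment the p needed for a call depends on how many probe sets change. In the real data only 8 probe sets were called between CC-S and CC-M, so these recovered shares need not hold there. For CC-M with VISUAL, where nothing was changed, it made 0 calls.

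Gene lists were tested with camera (preset correlation 0.01, 2-sided) on the brightest single-gene probe set of each gene, for lists with at least 3 measured genes: 7 of the 16 fixed lists. Adjustment was over the lists within a comparison, and camera with an estimated correlation and fry were run beside it. With an estimated correlation no call of any list or family held. In the camera self-test the shifted list was recovered and 8 of 200 unshifted lists had p under 0.05. The simulated genes varied independently of each other, so this check says nothing of lists whose genes vary together. Another 6 lists (further photosynthesis, further xylem and secondary wall, relatives of phloem regulators, DOF factors, further cell cycle, hypoxia) were added after the annotation was seen, before any change was looked at. Of 26 gene families named in advance by symbol stem, 12 had at least 8 measured genes and were tested as an exploratory set.

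The genes named in the text follow a rule fixed before the data were examined. In each comparison it takes the 10 largest rises and 10 largest falls among called single-gene probe sets whose group values do not overlap, up to 4 measured members of each fixed list with the smallest p, and 8 genes of interest, none of which was measured. Genes named outside this rule (families, added lists, glutaredoxins, organelle genes) were chosen after their values were seen. Of the added list entries, 2 whose symbol belongs to another locus were left out.

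The effect of sharing the VISUAL arrays was estimated with 50 simulations of unchanged groups, in which the VISUAL arrays were simulated too. Alternatives were quantile normalization, median centring of each array, leaving out the dimmest 40% of probe sets, fitting only the 6 arrays compared, eBayes without trend or robust, array weights, the replicate number as a block, a test against 1.5-fold, other list tests, the mean of a gene's probe sets, and leaving out each array in turn. A further 2 were added after seeing the data: only single-gene probe sets, and without the low-numbered block. Alternative pseudocounts were not run, because the table is on a log2 scale.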

Results

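Cotyledons of Arabidopsis thaliana (ecotype Col-0) were cultured in VISUAL-CC, a tissue culture in which leaf cells are turned into vascular cells and then into phloem companion cells (CC). Companion cells are the nucleated partners of the sieve elements and load sugar into the phloem. One-colour Affymetrix arrays measured transcript levels in 9 samples, all taken 96 hours after CC induction. The labels sort them into 3 groups of 3: CC-S, which induces CC differentiation strongly, CC-M, which induces it moderately, and VISUAL, which does not. The deposited values are log2 signals of 38408 probe sets, and array medians ran from 4.71 to 4.90. No label says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

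The first principal component held 42.3% of the variance and placed the VISUAL arrays at one end, CC-M in the middle and CC-S at the other end. CC-S replicate 5 had a score of 33.8 on it, against 54.0 and 55.5 for the other CC-S arrays and 11.5 to 26.0 for the CC-M arrays. The second component held 11.8% of the variance, and there CC-M did not lie between the other groups. Its arrays scored -42.2 to -14.67, against 16.15 to 30.29 for CC-S and -9.909 to 20.7 for VISUAL. Pairs of arrays correlated across probe sets with a mean r of 0.983 within CC-S, 0.985 within CC-M and 0.983 within VISUAL. Mean r was 0.981 between CC-S and CC-M, 0.971 between CC-M and VISUAL and 0.962 between CC-S and VISUAL.

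**Figure D1:**
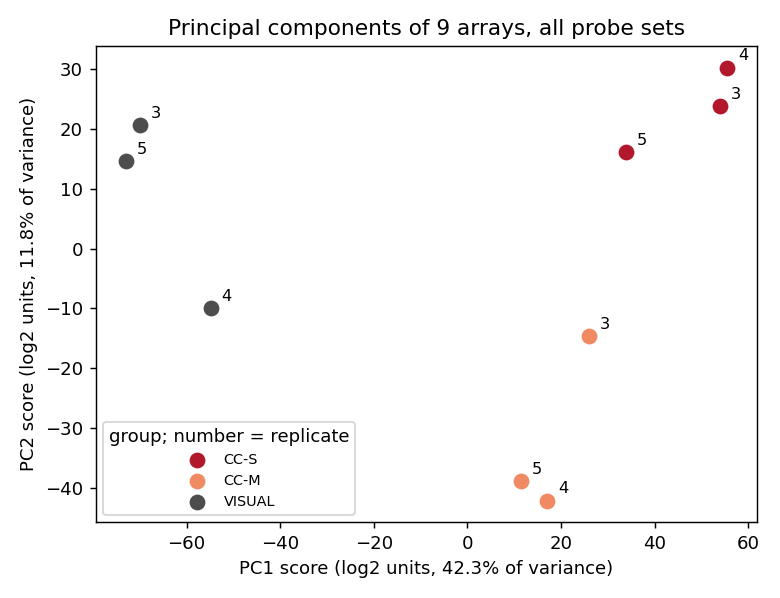
Scores of the 9 arrays on principal components 1 and 2 of the log2 signals of all probe sets; points are arrays, colours are groups and numbers are replicates. On component 1 the VISUAL arrays lie between -73.0 and -54.9 and every CC-S or CC-M array lies above 11. On component 2 every CC-M array lies below all CC-S and VISUAL arrays.

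The comparison of CC-S with VISUAL asks which transcripts differ where CC differentiation was strongly induced. SAPL (AT3G12730), a MYB-type transcription factor closely related to the phloem regulator APL and active in companion cells, rose 8.25-fold: its log2 signal was 8.57 ± 0.25 (SD, n = 3) in CC-S and 5.52 ± 0.59 (SD, n = 3) in VISUAL. SWEET11, a sucrose exporter of phloem parenchyma, rose 5.04-fold, and the auxin-induced transcription factor gene LBD16 rose 10.3-fold. The xylan synthesis gene IRX15, which acts in secondary walls of xylem, fell by 1.91 on the log2 scale, and the cytokinin response gene ARR15 fell by 2.95. Over all probe sets 7365 of 38408 were called at an adjusted p under 0.05 by limma's moderated test, 3882 higher and 3483 lower in CC-S, and 2591 of them changed at least 2-fold.

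The largest rises between CC-S and VISUAL were in 2 glutaredoxin genes, whose products are small redox proteins. AT4G15700 had a log2 signal of 9.31 ± 0.19 (SD, n = 3) in CC-S and 1.30 ± 0.21 (SD, n = 3) in VISUAL, a log2 change of 8.01 (limma adjusted p = 1.2e-06). Only 0.883% of probe sets had a mean over all arrays at or below that VISUAL value, so its fold rests on a signal near the bottom of the range. AT5G18600 rose by 6.21 on the log2 scale. AT3G18280, of the lipid transfer protein family, rose by 5.80, AT3G55240 by 5.15 and the GABA transporter gene AT1G08230 by 4.78. The class III peroxidase genes Prx37, AT4G08780 and AT5G64120 rose by 5.52, 4.27 and 3.99. Prx37 and AT4G08780 are related neighbouring genes, and how far their probes read each other was not analysed here. The expansin gene EXPA9 rose by 4.29 and AT2G44380 by 3.99.

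The largest fall was that of AT2G18490, a C2H2 zinc finger gene, with a log2 signal of 2.88 ± 0.47 (SD, n = 3) in CC-S and 7.74 ± 0.26 (SD, n = 3) in VISUAL (log2 change -4.85, limma adjusted p = 1.86e-05). AT3G57950 fell by 4.52 and AT3G28510 by 4.23, the beta-glucosidase gene BGLU28 fell 17.1-fold, and the glutathione transferase gene GSTU25 changed by -3.92. The calmodulin-like gene CML41 fell by 3.79, the methionine sulfoxide reductase gene MSRB8 by 3.62, AT1G13520 by 3.55, AT3G20340 by 3.46 and AT5G24200 by 3.37.

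Of the 20 companion cell genes fixed before the data were examined, 2 were measured, SAPL, which rose (limma adjusted p = 0.000222), and SWEET13, with a log2 change of 0.03 at a signal of 2.76 in VISUAL. Neither SUC2 nor any other of the 8 genes named in advance (SULTR2;1, APL, SMXL5, SEOR1, CESA7, PXY and CAB3) has a probe set named to it alone, and they were not analysed here. Of 5 early phloem regulators, PEAR2, a DOF transcription factor of the young phloem, rose by 0.99 and PAX, a protein kinase gene of the protophloem, fell by 0.57. OPS and CLE45 had log2 changes of 0.31 and -0.12, and the list as a whole had a camera adjusted p of 0.769. SWEET11 was the 1 measured phloem parenchyma gene (limma adjusted p = 0.0101). The call of PEAR2 ended without VISUAL replicate 3, 4 or 5, with adjusted p up to 0.0627.

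Of 3 measured xylem vessel genes, IRX15 and IRX10, both of xylan synthesis, fell by 1.91 and 1.03, and IRX15-L had a log2 change of -0.88, called only without CC-S replicate 5 (adjusted p = 0.0378) or with the replicate number as a block (0.0166). The list was lower by camera at an adjusted p of 0.0308, and all 3 genes fell when adjusted over the list alone. With an estimated correlation its adjusted p = 0.561. IRX15 and IRX15-L are close relatives whose probes may share signal. Of 6 measured procambium and cambium genes, the receptor kinase gene MOL1 rose by 0.62 and LHW, a bHLH factor of vascular cell division, by 0.50, while CLE41 and the receptor kinase gene PXL2 had log2 changes of 0.61 and 0.51 that were not called; CLE41 was called in 3 of 20 other settings (adjusted p = 0.0068 without VISUAL replicate 5) and PXL2 in 5 (0.0148 without CC-S replicate 5). The list was higher at an adjusted p of 0.0308, with 5 of 6 genes higher when adjusted over the list alone, but adjusted p = 0.197 with an estimated correlation. Without CC-S replicate 3 or 4, or VISUAL replicate 3, neither list was called, and the adjusted p reached 0.0608 for xylem and 0.0595 for procambium. Both lists also lost their call without the dimmest probe sets and with the mean of a gene's probe sets. With each array centred on its median the xylem list had a camera adjusted p of 0.0541. LHW lost its call without any of 5 arrays (adjusted p up to 0.11), and IRX10 lost its call without CC-S replicate 4 (adjusted p = 0.0528).

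Of 8 measured auxin response genes, LBD16 and GH3.5, which conjugates auxin to amino acids, rose by 3.37 and 2.52, and GH3.1 and IAA30 fell by 1.16 and 1.82; the list went both ways (camera adjusted p = 0.467). Both measured cytokinin response genes are type-A response regulators, and they moved apart: ARR15 fell by 2.95 (limma adjusted p = 0.000741) and ARR16 rose by 0.85. Of 4 measured cell cycle genes, the replication gene MCM7 rose by 0.91, and the aurora kinase genes AUR1, AUR3 and AUR2 had log2 changes of 0.78, 0.18 and 0.07 (list adjusted p = 0.238). EXPA8, the 1 measured brassinosteroid-induced gene, fell by 0.94. The lists fixed for other cell types held no called gene: 0 of 5 photosynthesis genes, with LHCB4.1 at -0.24 and RCA at 0.19 (list adjusted p = 0.769), and 0 of 3 stomatal genes, with FAMA at -0.46, SPCH at 0.35 and MUTE at -0.48 (list adjusted p = 0.698). Of 9 further photosynthesis genes, listed after the annotation was seen, PSB27, LHCB4.2 and HPR rose 2.14-fold, 1.51-fold and 1.34-fold and LHCB4.3 fell 2.14-fold (list adjusted p = 0.215). The senescence gene SWEET15 had a log2 change of 0.83 with an SE of 1.25, and the jasmonate gene PDF1.2 one of 0.37; neither was called. LHCB4.1 was called lower without VISUAL replicate 5 (-0.41, adjusted p = 0.0275), and FAMA in 8 of 20 other settings, among them quantile normalization (adjusted p = 0.0462) and median centring of each array (adjusted p = 0.0482).

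**Figure D2:**
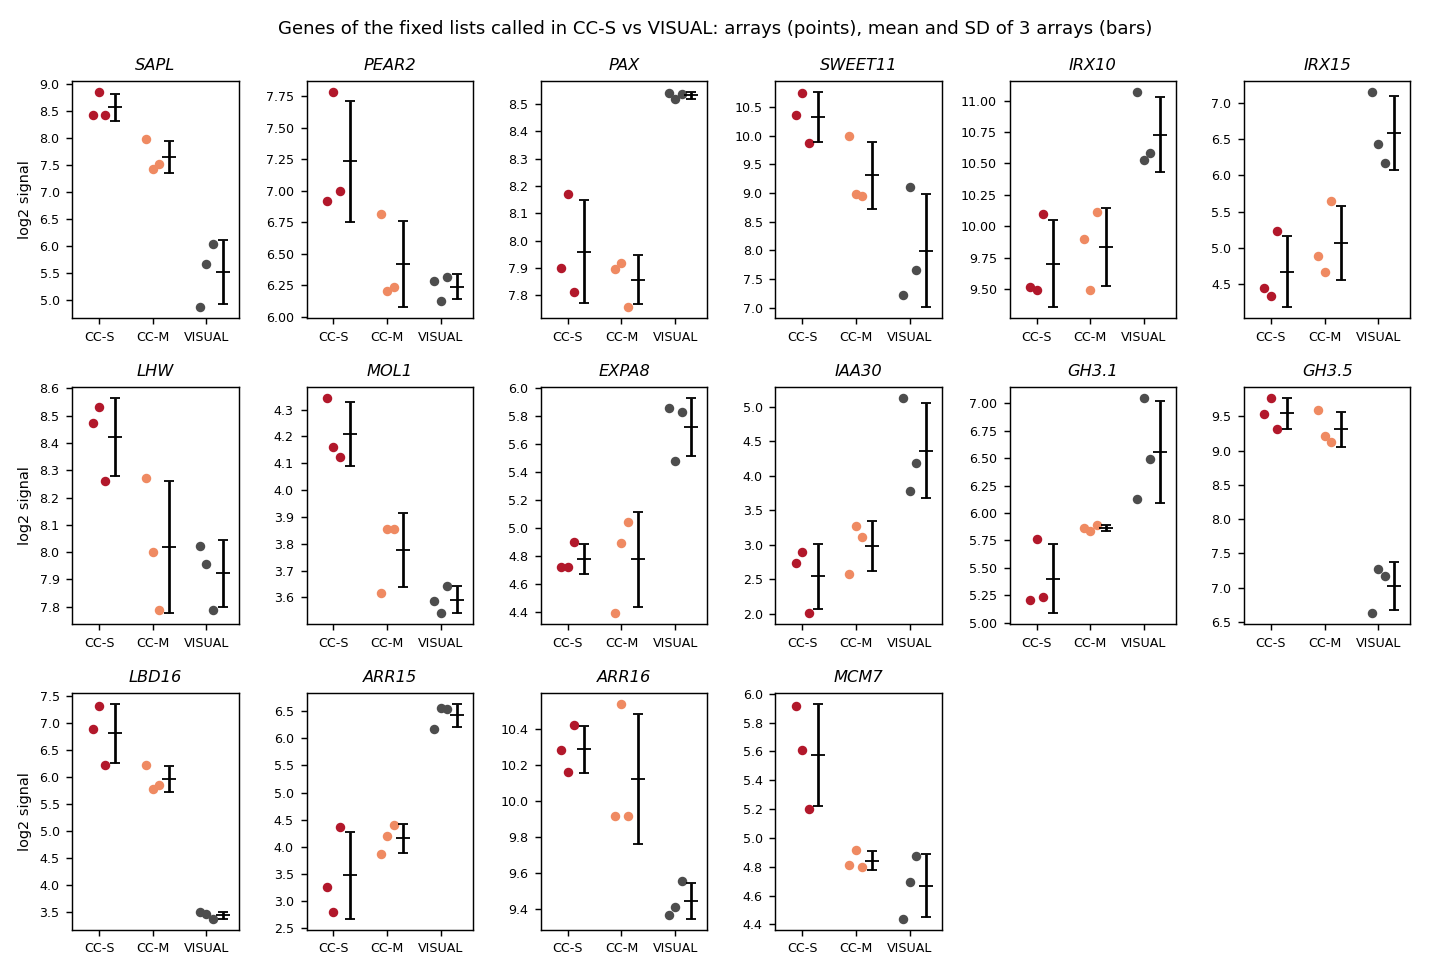
Log2 signals of the 16 genes of the lists fixed in advance that were called between CC-S and VISUAL; coloured points are arrays, and the black bars give the mean and SD of 3 arrays. LBD16 lies near 3.45 in VISUAL and at means of 6.81 in CC-S and 5.96 in CC-M, and each panel has its own axis, which does not start at 0.

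The 3 values of CC-S and those of VISUAL did not overlap at 32.6% of probe sets, where chance gives 10%. Testing for a change beyond 1.5-fold left 1212 calls, and with each array centred on its median the balance turned to 3270 higher and 3950 lower. Only 16722 probe sets name exactly 1 gene, of which 3372 were called (1704 higher and 1668 lower). Genes with a symbol rarely have such a probe set, and 42 of 259 genes of the fixed lists were measured.

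The comparison of CC-M with VISUAL asks the same of the moderate induction. SAPL rose 4.35-fold, from a log2 signal of 5.52 ± 0.59 (SD, n = 3) to 7.65 ± 0.30 (SD, n = 3; limma adjusted p = 0.00239). LBD16 rose 5.72-fold and GH3.5 rose 4.88-fold, while ARR15 fell by 2.27 on the log2 scale. SWEET11 had a log2 change of 1.31 with an SE of 0.484 and was not called (limma adjusted p = 0.131); it was called without VISUAL replicate 4 (adjusted p = 0.0171). In all, 4470 probe sets were called, 2493 higher and 1977 lower in CC-M, and 1432 of them changed at least 2-fold.

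AT4G15700 led here too, with a log2 change of 7.30 (limma adjusted p = 2.68e-06), followed by AT3G18280 at 5.43, AT5G18600 at 5.28, AT3G55240 at 4.26 and AT1G08230 at 4.15. Prx37 rose by 3.73, AT2G44380 by 3.58, AT3G04010 by 3.38 and the peroxidase genes AT4G33420 and AT5G64120 by 3.22 and 3.17. AT2G18490 fell by 4.14 and AT3G57950 by 3.70 (limma adjusted p = 0.000696). MSRB8 and GSTU25 each fell by 3.63, AT3G28510 by 3.18, AT5G24200 by 2.88 and CML41, AT5G60650 and the U-box gene PUB54 by 2.82 each. AT1G13520 fell by 2.74.

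Among the lists, SWEET13 had a log2 change of -0.10, PAX fell by 0.67, and PEAR2 and CLE26 had changes of 0.18 and 0.24 (early phloem list adjusted p = 0.423). IRX15 fell by 1.51 and IRX10 by 0.89, and the xylem list had an adjusted p of 0.061; it was called without CC-S replicate 5 (adjusted p = 0.0328) and without CC-M replicate 5 (adjusted p = 0.00956), and with the replicate number as a block (adjusted p = 0.0196). The procambium list, with CLE44 at 0.83 and CLE41 at 0.56, had an adjusted p of 0.0894 and no member called; CLE41 was called without VISUAL replicate 5 (adjusted p = 0.0156). IAA30 fell by 1.38 (auxin list adjusted p = 0.423), ARR16 rose by 0.68 and EXPA8 fell by 0.95. No cell cycle gene was called, with MCM7 at 0.17 and AUR2 at -0.72 (list adjusted p = 0.493). Neither was any of the photosynthesis genes (RCA at 0.26, called only with the replicate block, 0.0414; list adjusted p = 0.423) or stomatal genes (MUTE at -0.33, list adjusted p = 0.594). SWEET15 and PDF1.2 had changes of 0.89 and 0.13.

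Leaving out CC-M replicate 3, 4 or 5 gave 2735, 2450 and 2940 calls, leaving out VISUAL replicate 5 gave 2932, and testing for a change beyond 1.5-fold left 484. With each array centred on its median 1940 were higher and 2230 lower. The calls of IRX15, IRX10, ARR16 and IAA30 each ended without at least 3 single arrays (highest adjusted p 0.0967, 0.116, 0.088 and 0.15), and non-overlapping values held for 27.6% of probe sets, where chance gives 10%.

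The changes of CC-S and CC-M against VISUAL ran in parallel. Of the probe sets called, 2059 rose in both and 1753 fell in both, while 2 moved in opposite directions. Independent lists of these sizes would share 252 rises and 179.3 falls, a value that leaves out the shared VISUAL arrays, and 50 simulations of unchanged groups, which leave out the effects and give almost no calls, shared 0. The 3 VISUAL arrays were not split between the comparisons, so part of the excess in these counts may come from the shared controls. Of the CC-M rises 82.6% were also called as rises in CC-S, and of the CC-M falls 88.7% were also called as falls. Without CC-M replicate 4 the shared rises numbered 1201 and the shared falls 1032. The log2 changes correlated across probe sets with r = 0.82, where the simulations, with simulated VISUAL arrays shared by both comparisons, gave 0.50. Probe sets are not independent replicates. The covariance of the log2 changes was 0.232 against 0.0283 simulated, a difference of 0.203. Among the 8021 probe sets called in either comparison, 79.4% had the larger change in CC-S. This share partly restates the calls that chose these probe sets, since 3551 were called in CC-S only and 656 in CC-M only. SAPL was at 3.04 in CC-S and 2.12 in CC-M, ARR15 at -2.95 and -2.27, and LBD16 at 3.37 and 2.52.

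**Figure D3:**
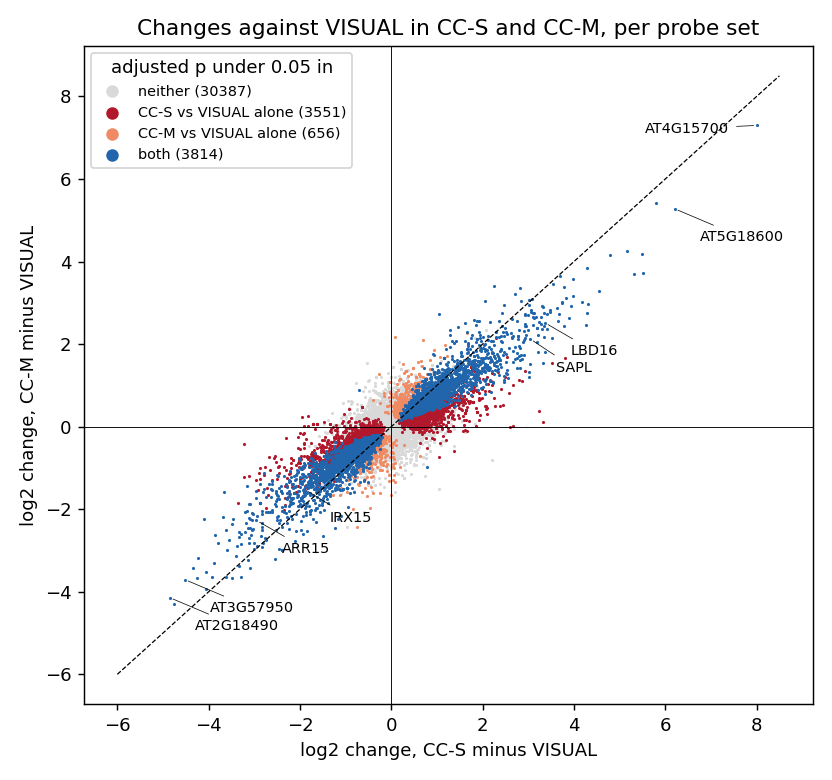
Log2 change of each of 38408 probe sets in CC-S minus VISUAL (horizontal axis) and CC-M minus VISUAL (vertical axis), coloured by the comparison in which it was called, with equal changes along the dashed line. The 3812 probe sets called in both in the same direction lie along the diagonal, with AT4G15700 at 8.01 and 7.30 and AT2G18490 at -4.85 and -4.14.

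The direct comparison of CC-S with CC-M asks what differs between strong and moderate induction. Only 8 probe sets were called by limma, 3 higher and 5 lower in CC-S, against 4935 at an unadjusted p under 0.05. Of these 8, 3 name a single gene. EXO, a gene known for its response to brassinosteroids, fell by 1.77 on the log2 scale: its signal was 6.11 ± 0.38 (SD, n = 3) in CC-S, 7.88 ± 0.12 (SD, n = 3) in CC-M and 8.02 in VISUAL (limma adjusted p = 0.0472). AT1G21326 rose by 1.25 and AT2G32880 by 1.13 (both limma adjusted p = 0.0346). These 2 genes had also risen in CC-M against VISUAL, with mean signals of 5.73, 6.95 and 8.20 for AT1G21326 and 7.06, 8.15 and 9.28 for AT2G32880 in VISUAL, CC-M and CC-S. They were the 2 probe sets called at both steps upward; 1 was called at both steps downward, and 2 were called at both steps in opposite directions.

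SAPL was higher in CC-S by 0.92 with an SE of 0.286, LBD16 by 0.85 and SWEET11 by 1.02, none of them called (adjusted p 0.21, 0.191 and 0.435); without CC-S replicate 5 LBD16 was called (1.14, adjusted p = 0.0475). The cell cycle list was higher in CC-S by camera (adjusted p = 0.00143; adjusted p = 0.226 with an estimated correlation): MCM7 differed by 0.73, AUR2 by 0.78, AUR1 by 0.72 and AUR3 by 0.48. None of these 4 was called over all probe sets, and 3 were when adjusted over the list alone. The median log2 change of that list was -0.12 from VISUAL to CC-M and 0.73 from CC-M to CC-S. The xylem list had medians of -0.89 and -0.23 at these steps, and the procambium list 0.19 and 0.18.

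No other list fixed in advance was called between CC-S and CC-M. PEAR2 differed by 0.81 and OPS by 0.39 (early phloem list adjusted p = 0.0803; called higher without the dimmest 40% of probe sets, 0.0495, and without CC-S replicate 5, 0.0465), PSAE-1 by -0.35 (photosynthesis list 0.0803), MOL1 by 0.43 and LHW by 0.40 (procambium list 0.126). IRX15 differed by -0.40 (xylem list 0.397), IAA29 by 0.67 (auxin list 0.602) and FAMA by -0.35 (stomatal list 0.651). SWEET13 differed by 0.12, EXPA8 by 0.01, ARR15 by -0.68, ARR16 by 0.17, SWEET15 by -0.06 and PDF1.2 by 0.24.

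The number of calls between CC-S and CC-M depended strongly on the setting, from 0 without CC-S replicate 3 or 4, CC-M replicate 4 or 5, or VISUAL replicate 3, and 1 without VISUAL replicate 4 or 5, to 309 without CC-S replicate 5 and 847 with arrays weighted by quality. EXO and AT2G32880 lost their calls without any of 8 arrays and AT1G21326 without any of 7, with adjusted p up to 0.209.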

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

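Settings that were added after seeing the data are the restriction to single-gene probe sets and the removal of the low-numbered block. The 7365 calls of CC-S with VISUAL and the 4470 of CC-M with VISUAL moved by over 1.5 times against 1.5-fold (1212 and 484), where a stricter threshold is tested, and among single-gene probe sets (3864 and 2391), where fewer are tested. Leaving out 1 array gave 5095 to 7043 and 2450 to 4666 calls, the lowest without CC-S replicate 4 and CC-M replicate 4, and the highest without VISUAL replicate 4; CC-M with VISUAL moved by over 1.5 times without any CC-M array or VISUAL replicate 5. No called probe set or named gene reversed in any setting. Centring each array on its median moved the share of higher calls from 52.7% to 45.3% in CC-S and from 55.8% to 46.5% in CC-M.

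The 8 calls between CC-S and CC-M became 42 with quantile normalization, 38 with median centring, 310 without the dimmest probe sets, 4 in the fit of 6 arrays, 0 without the trend, 847 with array weights, 0 against 1.5-fold, 179 among single-gene probe sets and 250 without the low-numbered block, and 0 to 309 without 1 array, highest without CC-S replicate 5. Fewer probe sets tested, and an intensity trend and prior refitted on them, bear on the counts of 310, 179 and 250. Otherwise the cause was not tested. All 8 remained in the settings with 42, 38, 310, 847 and 250 calls. Probe sets changing again in the same direction from CC-M to CC-S, 3 as reported, numbered 17, 15, 134, 1, 0, 290, 0, 75 and 107 in the same settings in that order, and 0 to 142 without 1 array.

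Shared rises numbered 273 and shared falls 173 against 1.5-fold, and 1067 and 994 among single-gene probe sets; without 1 array they ran from 1201 to 2280 and from 1032 to 1650. The correlation of log2 changes, 0.82, was 0.873 without the dimmest probe sets, 0.870 among single-gene ones and 0.862 without the low-numbered block, and 0.765 to 0.840 without 1 array.

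The xylem list of CC-S with VISUAL lost its call with median centring (adjusted p = 0.0541), without the dimmest probe sets (0.163), with an estimated correlation (0.561) and with the mean of a gene's probe sets (0.0616), and had 0.0138 to 0.0608 without 1 array. The procambium list lost it without the dimmest probe sets (adjusted p = 0.164), with an estimated correlation (0.197) and with the mean of a gene's probe sets (0.0996), and had 0.0138 to 0.0595 without 1 array. The cell cycle list of CC-S with CC-M lost it with an estimated correlation (adjusted p = 0.226), had 0.0834 in fry and had 0.00029 to 0.0159 without 1 array. Because fry tests a list against no change and camera against the other genes, a difference between them is no gain or loss of the same call. In fry alone, auxin response in CC-S with VISUAL (0.00121), which held 2 rises and 2 falls, and auxin response (0.00631) and procambium (0.00821) in CC-M with VISUAL were under 0.05. The cause was not tested.

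Of the named genes called in CC-S with VISUAL, 24 of 36 kept their call in every setting, 3 lost it without some array and 12 against 1.5-fold. In CC-M with VISUAL 23 of 30 kept it, and in CC-S with CC-M 0 of 3. Uncalled genes that gained a call in some setting were IRX15-L, PXL2, CLE41, LHCB4.1 and FAMA in CC-S with VISUAL, SWEET11, CLE41, RCA and GH3.3 (0.0482 without VISUAL replicate 4) in CC-M with VISUAL, and LBD16 in CC-S with CC-M.

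The labels do not say whether a replicate number marks a shared culture or day. Arrays with the same number deviated together with r from -0.0328 to 0.121, above 0.1 in 2 of 9 pairs. In 12 of 18 cases an array matched its own number best among the 3 arrays of another group. An effect shared by arrays of the same number is therefore not excluded, and the reported fit leaves it out. With the number as a replicate block there were 7365, 4479 and 10 calls in CC-S with VISUAL, CC-M with VISUAL and CC-S with CC-M, of which 6701, 3931 and 3 were among those reported. With the block, EXO lost its call between CC-S and CC-M (adjusted p = 0.0636) and IAA30 in CC-M with VISUAL (0.077). IRX15-L (0.0166) and FAMA (0.00758) in CC-S with VISUAL, and RCA (0.0414) and the xylem list (0.0196) in CC-M with VISUAL, gained one. The table gives no background, so how far low signals lie above it stays unknown.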

Other observations

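The tests on glutaredoxins, on nuclear photosynthesis genes and on the ratio of changes were chosen after the result was seen, and the rule for the mitochondrial genes was made stricter after their value was seen. Gene families were named before the files were opened, and the added lists after the annotation was seen. Transporters of the NPF family, which carry nitrate, peptides and glucosinolates, were called as a family only in CC-M against VISUAL. There 3 of 13 measured members rose and none fell (camera adjusted p = 0.00383, or 0.134 with an estimated correlation). In CC-S against VISUAL 4 of 13 rose and none fell (camera adjusted p = 0.177). The glucosinolate transporter gene GTR2 rose by 1.40 in CC-M and 1.85 in CC-S, AT2G26690 by 1.88 and 2.05, and AT1G59740 by 1.53 and 3.03. The SWEET family had 3 of 16 members higher in CC-S, SWEET11, SWEET1 and SWEET4 (family adjusted p = 0.25). Of 13 measured DOF factors outside the fixed lists, 6 rose in CC-S (adjusted p = 0.0121; 0.172 with an estimated correlation), among them AT2G28510 by 1.53 and AT4G24060 by 0.89, and 3 rose and 1 fell in CC-M (adjusted p = 0.0248; 0.16 with an estimated correlation). The further xylem list was lower in both, with PRX72 at -2.16 on the log2 scale in CC-S (list adjusted p = 0.0404; 0.172 with an estimated correlation) and MWL2 and SACL1 lower in CC-M (0.026; 0.16). With median centring the CC-S value was 0.0529. The further cell cycle list was higher in CC-S than in CC-M (adjusted p = 0.00511; 0.195 with an estimated correlation), with no member called; in CC-S against VISUAL the replication genes ICU2 and ASF1B rose by 0.95 and 0.68.

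The GSTU and UGT families went both ways. GSTU25 and GSTU22 changed by -3.92 and -1.89 in CC-S and by -3.63 and -1.96 in CC-M, and the glucosyltransferase genes UGT73B2, UGT73B3, UGT73B1 and UGT73B5 fell by 1.48, 1.37, 0.77 and 0.84 in CC-S, while neither family was called as a whole (adjusted p 0.715 for GSTU with 1 rise and 2 falls, 0.452 for UGT with 6 rises and 10 falls). The hypoxia list was higher in CC-M (adjusted p = 0.0381; 0.162 with an estimated correlation), where HUP36 rose by 1.37 and HUP26 fell by 0.52, and had 0.0526 in CC-S, or 0.0394 with quantile normalization. The further photosynthesis list was higher in CC-M (0.0248; 0.16 with an estimated correlation) with PSB27 up by 1.06 and LHCB4.3 lower, and had 0.215 in CC-S; relatives of phloem regulators had 0.816 in CC-S and 0.676 in CC-M. Adjusted p in CC-S against VISUAL was 0.177 for NPF, 0.25 for bHLH and XTH, 0.372 for CYP71, 0.452 for IAA, 0.687 for EXPA, 0.708 for CLE and 0.746 for PUB. Between CC-S and CC-M no family was called (lowest adjusted p 0.0844, XTH).

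For each comparison the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In CC-S with VISUAL the real split gave 7365 calls and the highest other 0, and in CC-M with VISUAL 4470 and 0. In CC-S with CC-M it gave 8 and the highest other 6. In each case 1 of the 10 splits, the real one, gave at least as many calls. Every other split mixes arrays of both groups, so a real group difference widens its spread and lowers its calls. The low counts of these splits are therefore no measure of what chance would give.

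Few probe sets were called between CC-S and CC-M although arrays of both groups separate. CC-S replicate 5, which lies nearer to CC-M than the other CC-S arrays, may widen the spread: 309 probe sets were called without it. That array was singled out by its position in these data, and leaving out the CC-S array nearest to CC-M can itself enlarge the difference. The count therefore does not decide this. The noisy low-numbered block may use up the allowance for multiple tests: 250 were called without it. Leaving the block out also refitted the intensity trend and the prior of the test. That count therefore does not decide this either. Whether CC-M shares most of the CC-S change was asked through the ratio of the CC-M change to the CC-S change. Over 2591 probe sets called at 2-fold in CC-S against VISUAL its median was 0.696 (quartiles 0.523 and 0.843). Of these probe sets 98.7% changed in the same direction. Over all probe sets the slope was 0.672, against 0.50 (0.487 to 0.518) in simulated unchanged groups. The covariance was 0.232 against 0.0275 to 0.0298 simulated, so independent noise in the shared VISUAL arrays alone gave less than was observed. A shift common to all VISUAL arrays was not simulated. How large the shared part is stays open, because both changes share the VISUAL arrays and no simulated value was made for these 2591.

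Glutaredoxins of the class of AT4G15700 were listed after its rise was seen. Of 19 measured, 7 rose in CC-S against VISUAL and none fell, and 5 rose in CC-M; the counts were the same with quantile normalization and median centring. All 5 copies of a tandem cluster rose in CC-S, AT4G15670 by 3.77, AT4G15660 by 3.52, AT4G15690 by 2.32 and AT4G15680 by 1.86, and 2 of 14 outside it, AT5G18600 and AT2G30540. Signal shared between the near-identical copies may account for part of the cluster, which stays open: the median log2 change outside it was 0.227, and this would be low with shared signal and with copies regulated together. Whether the family rises as a set stays open too: the 17 members outside the largest rises had a camera p of 0.00115, and 0.0944 with an estimated correlation. These 17 still held AT4G15670, AT4G15660, AT4G15690 and AT4G15680 of the cluster, and the family was picked from these data. The test therefore does not show a rise beyond the cluster.

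The RPS family as measured here is mostly plastid-encoded, and it was higher in CC-S (adjusted p = 0.00613; 0.338 with an estimated correlation) and CC-M (0.00383; 0.333). Of 63 plastid-encoded genes, 24 rose in CC-S and 12 in CC-M against VISUAL, with 0 lower, and medians of 0.171 and 0.144; with median centring 19 and 9 rose. A larger share of organelle RNA in the extracts may be the cause: 11 mitochondrially encoded genes had a median of 0.0897 in CC-S against 0.171 for the plastid ones, with 0 called, and did not differ clearly from the plastid genes (permutation test, 2-sided, p = 0.335). Their median was 0.0485 against 0.174 with quantile normalization and 0.0231 against 0.104 with median centring. More photosynthetic cells may be another: 14 nuclear photosynthesis genes had a median of 0.0532 in CC-S (permutation p = 0.294). In CC-M the medians were 0.205 for the nuclear, 0.0241 for the mitochondrial and 0.144 for the plastid genes, and no permutation test was run there. The permutation tests of CC-S shuffled genes, which were read on the same arrays and may vary together. Their p-values therefore measure the spread between genes and not between samples. The explanations cannot be told apart, because the classes overlap within their spread.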
